A study of Mus musculus with 8 samples.

How the data were processed

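RNA of whole mouse lung was measured on 8 arrays of an Affymetrix mouse expression array, 2 arrays in each of 4 treatment groups. Per the labels, mice received oil or retinoic acid on day 3 and saline or dexamethasone on day 4, after which the lungs were frozen for RNA extraction. The groups were taken from the sample titles: Dex, RA and RA-Dex name their treatments, and Dil, which no label defines, was taken as the arm given oil and saline because it is the only arm left. Replicates are lettered a and b. The labels do not say whether a and b are separate animals, pools or repeated hybridizations, so the p-values measure only the spread between these samples. Doses, strain and the time of collection are not given in the sources used here.

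The deposited values are intensity signals on a linear scale, with 1 value per probe set and array, and the values themselves show that each array had been scaled to a common level. The mean after trimming 2% at each end was 800.4 on every array, with a ratio of 1.00004 between the highest and the lowest. The scaling software is not given in the sources used here, and no detection calls were used. Because the trimmed means differed by less than the limit of 1.1 set before the data were examined, the values were not normalized again. Signals under 85.3, the pooled 25th percentile of all arrays, were set to that floor, and values were then taken as log2.

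Of 12488 probe sets, 66 control probe sets were left out. The remaining 12422 were kept for testing if their mean log2 over the 8 arrays was above the pooled 40th percentile, a signal of 200.8, which left 7309. The filter took no account of group. Gene symbols came from the probe annotation of the array, dated 2016, and were brought to current symbols by Entrez ID through a table of mouse genes (assembly GRCm38.p6, used for names only). Of the 12422 probe sets, 10833 had 1 symbol, 10817 of which were matched by Entrez ID, 396 had several symbols and 1193 had none. The 7309 tested probe sets included 6616 with 1 symbol, which stood for 5618 genes.

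The tests were run with limma 3.58.1 in R 4.3.3. Each probe set was fitted with 1 mean per group, and the moderated test of limma (eBayes with an intensity trend, two-sided) was applied to 8 contrasts. These were the dexamethasone effect averaged over the day 3 treatment, the retinoic acid effect averaged over the day 4 treatment, Dex against Dil, RA-Dex against RA, RA against Dil, RA-Dex against Dex, RA-Dex against Dil, and the interaction, which is the dexamethasone effect after retinoic acid minus that without it. All 8 arrays entered the same fit, with 4 residual degrees of freedom and 6.69 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the 7309 probe sets of each contrast, and an adjusted p under 0.05 counted as a change. Errors are standard errors (SE) of the log2 fold change from the fit.

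Altogether 22 gene lists for pathways and cell types of the developing lung, and for tissues that dissection could carry along, were fixed before the data were examined. Each gene was represented by its probe set of highest mean signal. The shift of each list was tested with camera of limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 22 lists of a contrast. The test with an estimated correlation uses the 4 residual degrees of freedom of the fit, and a call that is lost with it is given with that p. Counts adjusted over the list alone are given beside the counts over all genes. A further 8 lists were chosen after the data were seen and are used in the closing section, apart from the squamous epithelium and skeletal muscle markers, whose signals in the Dil arrays are also given before it.

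Genes were named by a rule written before the data were examined. In each contrast these were the 10 largest rises and 10 largest falls past the threshold among genes with 1 symbol whose compared groups did not overlap, up to 4 members of each list by smallest p, and a set of genes always given where measured: Kdr, Flt1, Eln, Fkbp5, Cdkn1a, Rarb, Crabp2, Tsc22d3 and Nr3c1. Of these, Rarb had no probe set of its own here, and Crabp2, Tsc22d3 and Nr3c1 were below the filter and not tested. Where another tested probe set of a named gene differed in sign, the text says so. Any gene named outside the rule is marked as chosen after its values were seen.

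The alternatives, each changing 1 choice, were quantile and cyclic loess normalization, no filter, a stricter filter at the pooled 60th percentile, a pseudocount in place of the floor, no intensity trend, a robust variance model, the replicate letter as a block, a minimum log2 fold change of 0.5, the mean over all probe sets of a gene, and the fit without each array in turn, in which a group left with 1 array is assumed to vary like the others. Fits without both Dil or both Dex arrays were added after the data were seen.

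The procedure was tested on simulated data of 7309 probe sets with 50 changed probe sets per size. For the dexamethasone average, 20%, 78%, 100% and 100% of the probe sets changed by 0.5, 1, 1.5 and 2 log2 units were called, and for Dex against Dil 6%, 42%, 88% and 94%. Of 7079 unchanged probe sets, 0.0989% and 0.127% were called in these contrasts. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.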

Results

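Gene expression was measured in the lungs of young mice that had received oil or retinoic acid on day 3 and saline or dexamethasone on day 4. The series is titled for the inhibition and the protection of alveolar septation, the process by which the walls of the lung's air sacs are subdivided after birth. Glucocorticoids such as dexamethasone are known to stop septation in newborn rodents, and retinoic acid, the active form of vitamin A, is known to promote it. The 4 groups, Dil (oil and saline), Dex, RA and RA-Dex, had 2 arrays each. Median signals per array lay between 316 and 342, and 23.4% to 25.7% of the probe sets of an array were at or under the floor of 85.3. Across genes, log2 signals correlated at 0.945 to 0.965 between the arrays of a group, at 0.938 to 0.964 between arrays that shared the day 4 treatment but not the group, and at 0.913 to 0.942 between arrays that differed in the day 4 treatment.

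The contrast of the 4 dexamethasone arrays with the 4 others asks what the glucocorticoid changed in the lung, averaged over the day 3 treatment. Genes known as direct glucocorticoid targets rose steeply. Zbtb16, a zinc-finger transcription factor, rose 15.7-fold (log2 fold change 3.97 ± 0.141 SE, n = 4 against 4, adjusted p = 1.43e-07), and Fkbp5, a chaperone that restrains the glucocorticoid receptor, rose 5.24-fold (2.39 ± 0.114, adjusted p = 8.84e-07). Igfbp3, a secreted protein that binds insulin-like growth factors, rose 10.4-fold (3.38 ± 0.132, adjusted p = 1.43e-07), and Cdkn1a, an inhibitor of the cell cycle, rose 3.83-fold (1.94 ± 0.135, adjusted p = 1.2e-05). Kdr, the receptor through which vascular endothelial growth factor acts on endothelium, fell to 0.551 of its level (-0.86 ± 0.122, adjusted p = 0.00148). Meox2, a homeobox gene of mesenchyme and vessels, fell to 0.24 (-2.06 ± 0.154, adjusted p = 1.81e-05), and Gja4, a gap junction protein of arterial endothelium, fell to 0.37 (-1.44 ± 0.135, adjusted p = 7.83e-05). In all, 572 probe sets changed, of which 311 rose and 261 fell.

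Other large rises after dexamethasone were the sulfotransferase Sult1a1 (3.20 ± 0.185), the vasodilator peptide adrenomedullin, Adm (2.84 ± 0.235), the activin antagonist follistatin, Fst (2.81 ± 0.256), Pdk4, which holds back glucose oxidation (2.55 ± 0.159), the kinase Map3k6 (2.56 ± 0.163), Otulinl (2.58 ± 0.157), xanthine dehydrogenase, Xdh (2.40 ± 0.157), and Lpin1, an enzyme of lipid synthesis (2.59 ± 0.356, adjusted p = 0.0892 with no filter). Other large falls were Erdr1 (-2.99 ± 0.112), Rangrf (-1.73 ± 0.373), the pyrimidine synthesis enzyme Cad (-1.64 ± 0.248), the leukocyte adhesion molecule Vcam1 (-1.63 ± 0.243, adjusted p = 0.0837 with no filter), the netrin receptor Unc5c (-1.60 ± 0.147), the chemokine Cxcl12 (-1.60 ± 0.129), the alcohol and retinol dehydrogenase Adh1 (-1.49 ± 0.125) and St8sia2, which builds polysialic acid (-1.45 ± 0.142). The call of Rangrf was lost without RA replicate b (adjusted p = 0.0576), without RA-Dex replicate b (0.06) and with no filter (0.135). Because 1 or 2 arrays on their lower side were at the floor, the sizes given for Sult1a1, Fst, Lpin1, Rangrf and Cad depend on the floor. The averaged falls of Erdr1 and Cad rest mostly on the Dex arm, which stood apart from all other arrays. Signals of Cad were 63.4 and 67.8 in Dex, 368 and 286 in RA-Dex, and 634 and 428 in RA. Those of Erdr1 were 260 and 307 in Dex, 5591 and 5723 in RA-Dex, and 14030 and 12290 in RA.

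As a list, the glucocorticoid-responsive genes shifted upward with dexamethasone, with a median of 1.17. Of 25 measured members, 19 rose, 0 fell and 6 did not pass (20 and 0 adjusted over the list alone; camera adjusted p = 3.11e-29, and 0.00462 with an estimated correlation). They included Ddit4, an inhibitor of growth signalling (2.16 ± 0.11), the transcription factor Cebpd (2.04 ± 0.115), the phosphatase Dusp1 (1.17 ± 0.11) and Nfkbia, which holds back NF-kappaB (1.37 ± 0.13). Dusp1 and Nfkbia are outside the naming rule and were chosen after their values were seen.

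Among 25 growth factor and morphogen genes of septation, 4 rose and 3 fell with dexamethasone (4 and 7 adjusted over the list alone). Besides Igfbp3, the rises included Igfbp6 (1.02 ± 0.109) and Pdgfra, the receptor carried by the precursors of septal myofibroblasts (0.87 ± 0.119), while its ligand Pdgfa fell (-0.65 ± 0.107, adjusted p = 0.00351). With no filter 1 gene fell. The list as a whole did not shift past the threshold. The elastic fibre genes did not shift as a list (median -0.02, mean 0.08, camera adjusted p = 0.831), and of 12 measured only Lox, the enzyme that crosslinks elastin, passed (1.69 ± 0.134, with 1 other probe set of opposite sign; with quantile normalization 2 genes rose). Elastin itself, Eln, had a log2 fold change of 0.19 ± 0.103 (adjusted p = 0.347). In the endothelial and vascular growth list of 22, Kdr fell, and the lymphatic growth factor Vegfc (0.93 ± 0.197) and endothelin 1, Edn1 (0.68 ± 0.185) rose. Flt1, like Kdr a receptor of vascular endothelial growth factor, had a value of 0.05 ± 0.151 (adjusted p = 0.892). Vegfc lost its call without Dex replicate a (adjusted p = 0.0569), Dex replicate b (0.0506) or RA-Dex replicate b (0.0887), and Edn1 lost its call without Dex replicate a (0.154), Dex replicate b (0.0994), Dil replicate b (0.155), RA replicate a (0.123), RA-Dex replicate a (0.17) or RA-Dex replicate b (0.0583). Both were lost with no filter (adjusted p = 0.117 and 0.247), and Edn1 with no intensity trend (0.109).

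The cell cycle genes did not shift as a list after dexamethasone. Of 34 measured, 6 fell and 1 rose (7 and 3 adjusted over the list alone), and the median of 0.15 did not pass (camera adjusted p = 0.831). The falls included the replication licensing genes Mcm5 (-1.01 ± 0.14), Mcm3 (-0.89 ± 0.125), Mcm2 (-0.75 ± 0.138) and Mcm7 (-0.70 ± 0.135). Ccnb2, a cyclin of mitosis chosen here after its value was seen, rose (0.45 ± 0.097). The count of 1 rise was 0 without Dex replicate a, Dex replicate b, RA-Dex replicate a or RA-Dex replicate b, with no intensity trend and with a minimum log2 fold change of 0.5, 2 without Dil replicate a and 3 without RA replicate a. Of 17 immediate early and stress genes, 5 rose and 1 fell (3 and 0 with no filter, and 0 falls with the stricter filter), with rises of the transcription factor Fos (2.17 ± 0.136) and the stress genes Gadd45g (1.93 ± 0.155) and Gadd45b (1.14 ± 0.146).

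In the epithelium, the alveolar type I cell list of 6 shifted upward with dexamethasone by a median of 0.22 (camera adjusted p = 0.0203), with 2 rises (3 adjusted over the list alone), Hopx (0.62 ± 0.094, adjusted p = 0.00207) and Pdpn (1.15 ± 0.224, adjusted p = 0.0097). That shift was lost with an estimated correlation (adjusted p = 0.40), with no intensity trend (0.056) and without RA replicate a (median 0.148, adjusted p = 0.178), and without RA replicate b the median was 0.377 (0.0012). The call of Pdpn was lost without RA-Dex replicate b (adjusted p = 0.0579) and with no filter (0.167). Of 9 alveolar type II cell and surfactant genes, 2 fell, among them Lpcat1, which makes surfactant lipid (-0.70 ± 0.111), and 0 rose (2 and 1 adjusted over the list alone). The 2 falls became 1 without Dex replicate b or RA-Dex replicate a, with no filter and with no intensity trend. Of 4 airway genes 0 passed in limma, which gave 1557 of all probe sets an unadjusted p under 0.05. Lpl, the lipase of lipid storage, rose 4.99-fold (2.32 ± 0.196), alone among 12 genes of its list (2 rose under both normalizations and with no intensity trend), and the cholesterol synthesis enzyme Sqle fell (-0.74 ± 0.132), alone among 10. Of 12 protease and inhibitor genes 3 rose, led by Timp3 (1.04 ± 0.116) and the cathepsin Ctsl (0.66 ± 0.115).

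Among the blood cell lists, the macrophage markers shifted downward by a median of -0.33, with 3 falls and 1 rise among 14 (7 and 1 adjusted over the list alone), and the B cell markers by -0.51, with 3 falls among 8 (4 adjusted over the list alone). Both had a camera adjusted p of 0.0203, and both calls were lost with an estimated correlation (adjusted p = 0.40 for each). The signalling adaptor Tyrobp (-0.82 ± 0.123) and the antibody heavy chain Ighm (-0.81 ± 0.122) were among the falls. Of the macrophage counts, the 3 falls became 1 without Dex replicate a, Dex replicate b or RA replicate a, and the 1 rise became 0 without those arrays, Dil replicate b, RA-Dex replicate a or RA-Dex replicate b and under both other filters. The 3 B cell falls became 1 without RA replicate b or RA-Dex replicate a and with no filter. The macrophage shift was lost without RA-Dex replicate a (adjusted p = 0.0544) and the B cell shift without Dex replicate a (adjusted p = 0.0519). With no filter the macrophage median was -0.186 (adjusted p = 0.104), no intensity trend also ended that call (0.056), and the stricter filter ended the B cell call (0.272). In the neutrophil list of 7 only Lcn2 passed (1.02 ± 0.107, with 1 other probe set of opposite sign; 2 rose with no filter). The retinoid, collagen, smooth muscle, T cell, erythroid, heart and skeletal muscle, and inflammatory lists did not shift past the threshold. Median, mean and test differed in sign for the elastic fibre, type II cell, endothelial, protease, neutrophil and immediate early lists, the last with a median of -0.10 and a mean of 0.25.

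Of the 62 named genes called for the average effect of dexamethasone, 42 stayed called under all the alternatives run for them, and 0 reversed. The count of 572 fell to 349 with no filter, 269 of them shared with the 572, and to 309 without RA-Dex replicate b, 361 without Dex replicate a and 369 without Dex replicate b.

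**Figure D1:**
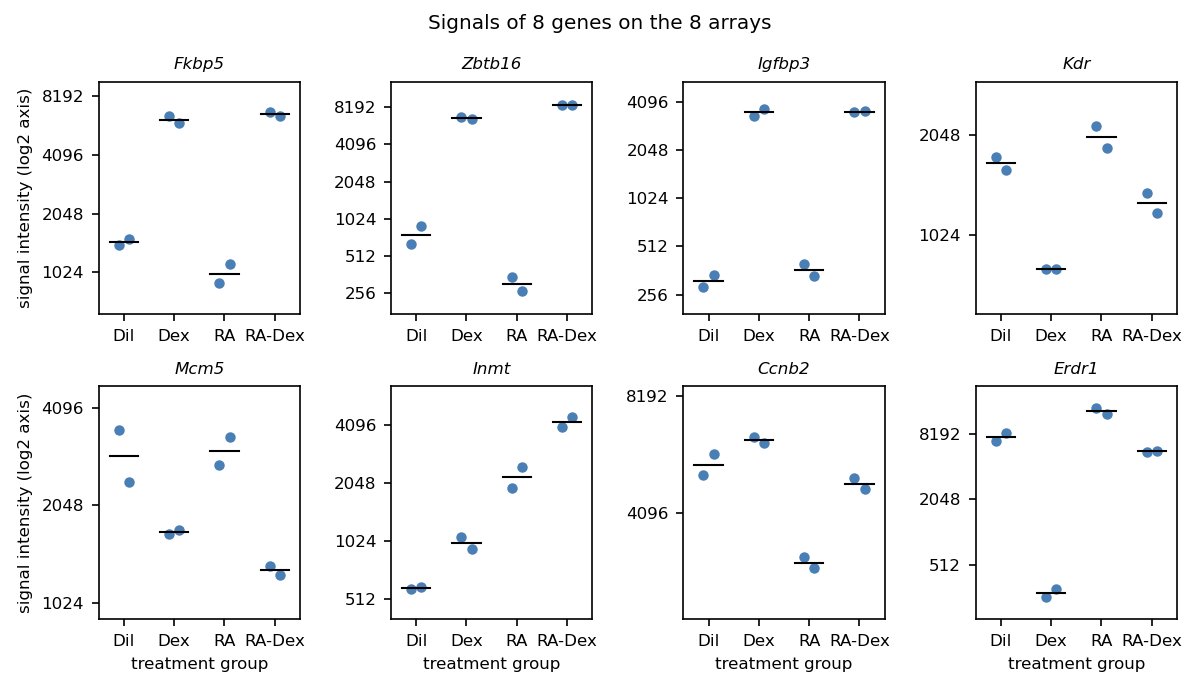
Signal intensity of 8 genes (log2 axis) on each array, by treatment group; points are the replicates and bars their geometric means. Fkbp5, Zbtb16 and Igfbp3 were higher in both dexamethasone groups, Kdr and Mcm5 were lower, Inmt was highest in RA-Dex, and Erdr1 had a mean of 283.5 in Dex against 5657 in RA-Dex.

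Dex against Dil, 2 arrays against 2, asks what dexamethasone did without retinoic acid. Kdr fell to 0.48 of its level (log2 fold change -1.06 ± 0.173, adjusted p = 0.00718), Igfbp3 rose 11.2-fold (3.49 ± 0.186), Zbtb16 8.81-fold (3.14 ± 0.199) and Fos 5.94-fold (2.57 ± 0.192). Fgfbp1, a carrier of fibroblast growth factors, rose at least 6.41-fold from Dil arrays that were both at the floor, and Map3k6 (2.57 ± 0.231) and Otulinl (2.69 ± 0.222) rose. Erdr1 fell (-4.77 ± 0.159), Cad fell to at most 0.165 of its level, with both Dex arrays at the floor (adjusted p = 0.0557 with no filter), and Cxcl12 fell to 0.269 (-1.89 ± 0.182). Altogether 146 probe sets rose and 90 fell. The call of Kdr was lost without Dil replicate a (adjusted p = 0.0513), Dex replicate a (0.0664) or Dex replicate b (0.0686), although its log2 fold change then stayed at -0.99, -1.06 and -1.06.

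By list, 17 of the 25 glucocorticoid-responsive genes rose in Dex against Dil and 0 fell (19 and 0 adjusted over the list alone; median 1.18, camera adjusted p = 1.02e-27, and 0.00514 with an estimated correlation). The smooth muscle and myofibroblast markers had a median of -0.33 (camera adjusted p = 0.00651), the B cell markers -0.44 (0.0425), and the heart and skeletal muscle markers -0.57 (0.000216). These calls were lost with an estimated correlation (adjusted p = 0.299, 0.384 and 0.125). Of their 13, 8 and 9 measured genes 1, 3 and 1 fell and 0 rose (6, 3 and 5 falls and 1, 0 and 0 rises adjusted over the list alone). The 1 smooth muscle and the 1 muscle fall became 0 without either Dil, either Dex or either RA-Dex replicate, with no filter and with no intensity trend, and the muscle count was 3 without either RA replicate and with the stricter filter and 2 with quantile normalization. The 3 B cell falls became 0 without Dil replicate b or Dex replicate b and with no filter, and 1 without Dex replicate a, RA-Dex replicate a or RA-Dex replicate b, with the stricter filter and with no intensity trend. The smooth muscle call was also lost without Dex replicate a (adjusted p = 0.0667), and the B cell call without Dex replicate a (0.249), Dil replicate a (0.0701), Dil replicate b (0.0665), RA-Dex replicate a (0.0534) or RA-Dex replicate b (0.0553). The B cell median was -0.264 with no filter (adjusted p = 0.0627), -0.182 without Dex replicate a and -0.697 without Dex replicate b (0.00313), and with the stricter filter its adjusted p was 0.191. Skeletal muscle and squamous epithelium transcripts stood high in the Dil arrays: in 12 of 23 such markers (52.2%), listed after the data were seen, both Dil arrays were above all 6 others, where chance gives 3.57% and all probe sets gave 5.3%. The count of 236 fell to 96 with no filter, 112 with no intensity trend, 112 without Dil replicate b, 96 without Dex replicate a and 80 without Dex replicate b.

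RA-Dex against RA, again 2 arrays against 2, asks what dexamethasone did after retinoic acid. Zbtb16 rose 27.8-fold (log2 fold change 4.80 ± 0.199, adjusted p = 8.42e-07), Sult1a1 15.1-fold (a size that depends on the floor, at which 1 of 2 RA arrays was), Igfbp3 9.72-fold (3.28 ± 0.186), Pdk4 7.87-fold (2.98 ± 0.225) and Fkbp5 6.53-fold (2.71 ± 0.161). Meox2 fell to 0.212 (-2.24 ± 0.218), St8sia2 to 0.31 (-1.69 ± 0.201) and the DNA repair gene Ercc1 to 0.222 (-2.17 ± 0.252). Ercc1 was low in the RA-Dex arm alone, with signals of 158 and 172 there and 747 and 731 in RA. It was at 694 and 552 in Dex and 530 and 427 in Dil, so dexamethasone without retinoic acid did not lower it. Kdr had a value of -0.66 ± 0.173, which did not pass (adjusted p = 0.0678). Altogether 167 probe sets rose and 89 fell.

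In RA-Dex against RA, 15 of the 25 glucocorticoid-responsive genes rose and 0 fell (19 and 0 adjusted over the list alone; median 1.0, camera adjusted p = 1.28e-28, and 0.00483 with an estimated correlation). The macrophage markers had a median of -0.32 (camera adjusted p = 0.00317), with falls of Tyrobp and the pore protein Mpeg1 among 14, and the type I cell (0.34), B cell (-0.58) and inflammatory (-0.54) lists each had a camera adjusted p of 0.0496. With an estimated correlation these 4 lists had adjusted p = 0.316, 0.492, 0.492 and 0.538. The inflammatory values rest on Vcam1, Ccl6, Ccl9 and Icam1. The probe sets of the other members, among them Tnf, Il1b, Il6 and Cxcl1, were below the filter. Adjusted over the list alone, 5 macrophage genes, 1 B cell gene and 1 inflammatory gene fell and 2 type I genes rose, and over all genes 1 type I gene, Pdpn, rose, 1 inflammatory gene, Vcam1, fell and 0 B cell genes passed in limma. Pdpn lost its call without RA replicate a (adjusted p = 0.121), RA-Dex replicate a (0.0924) or RA-Dex replicate b (0.244), and Vcam1 without RA-Dex replicate a (0.0752). With no filter the calls of Pdpn, Vcam1 and Mpeg1 were lost (adjusted p = 0.263, 0.162 and 0.187), and with no intensity trend those of Pdpn and Mpeg1 (0.107 and 0.0957). Both normalization alternatives, no filter and the stricter filter ended the type I, B cell and inflammatory calls. With no intensity trend the type I and inflammatory calls were lost (adjusted p = 0.0901 and 0.0845), and with the mean over all probe sets of a gene the inflammatory call (0.136), which was kept in 5 of 17 settings. With no filter the inflammatory median was -0.248 (adjusted p = 0.237) and the macrophage median -0.185 (0.015). The type I call was also lost without RA replicate a (adjusted p = 0.511) or RA-Dex replicate b (0.109), the B cell call without Dil replicate a (0.0507), RA replicate a (0.144), RA replicate b (0.124) or RA-Dex replicate b (0.162), and the inflammatory call without Dex replicate a (0.0505), Dex replicate b (0.0512), Dil replicate a (0.0507), RA replicate b (0.593) or RA-Dex replicate a (0.364). Without RA replicate a or RA-Dex replicate b the type I median was 0.123 and 0.147, and without RA-Dex replicate b the B cell median was -0.32. The inflammatory median was -0.819 without RA replicate a (adjusted p = 0.00964), -0.255 without RA replicate b, -0.192 without RA-Dex replicate a and -0.981 without RA-Dex replicate b (0.00161). The call of Tyrobp was lost without either RA-Dex replicate (adjusted p = 0.0555 for a, 0.077 for b), and that of Mpeg1 without Dex replicate a (0.0537), Dex replicate b (0.0528), RA replicate a (0.121), RA replicate b (0.077) or RA-Dex replicate a (0.231). The count of 256 fell to 143 with no filter, 126 with no intensity trend, 107 without RA-Dex replicate a and 81 without RA-Dex replicate b.

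The effects of dexamethasone with and without retinoic acid share no arrays, so they can be set side by side. Of the probe sets called, 128 were called in both, 97 as rises and 31 as falls, where independent calls would give 3.34 and 1.1. The calls are not independent, because both contrasts use the same variance per probe set from the same fit. A probe set of low variance is favoured in both, so 3.34 and 1.1 are too low as a measure of chance. Of those called in Dex against Dil, 94.9% had the same sign in RA-Dex against RA, and the slope of the effect after retinoic acid on that without it was 0.723. In the other direction these were 95.7% and 0.774. Over all 7309 probe sets Pearson's r was 0.495 and Spearman's rho 0.378, and single arrays gave r between 0.201 and 0.433; these are correlations across genes, which are not independent replicates. Fkbp5, Zbtb16, Igfbp3, Cdkn1a, Ddit4, Lox, Fos and Gadd45g were called in both contrasts under every alternative run for named genes.

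**Figure D2:**
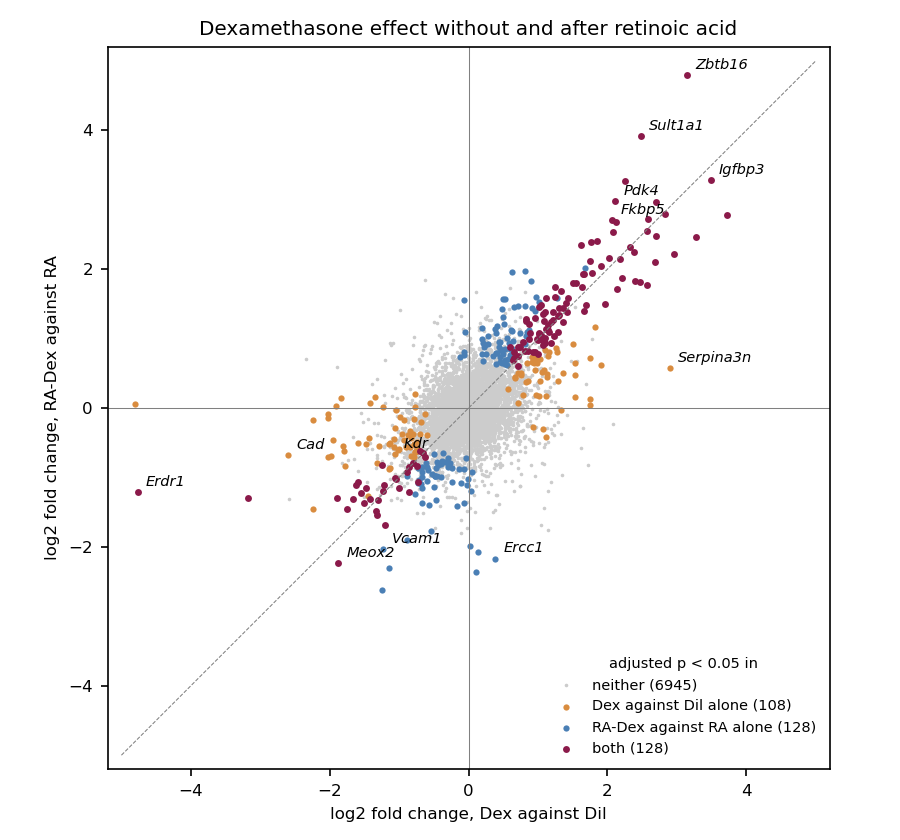
Log2 fold change of each tested probe set in Dex against Dil (horizontal) and in RA-Dex against RA (vertical), coloured by the contrast in which its adjusted p was under 0.05; the dashed line marks equal effects. The 128 probe sets called in both lie in the upper right (97) or the lower left (31), and Erdr1 lies far to the left of the line.

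The interaction asks directly whether the dexamethasone effect differed with retinoic acid. It does not answer the question of protection alone. An effect of retinoic acid of the same size with and without dexamethasone would not show in it, and RA-Dex against Dex bears on that. The simulated data held no interaction, so how often a true one would be called is not known. In the interaction only Erdr1 passed, with a log2 value of 3.55 ± 0.225 (adjusted p = 6.8e-05, n = 2 in each of 4 groups). Its 1 other tested probe set was of opposite sign, at -0.29. Its mean signal was 7713 in Dil, 283.5 in Dex, 13160 in RA and 5657 in RA-Dex. For Kdr the interaction was 0.40 ± 0.245 (adjusted p = 0.898), so a difference between its effects in Dex against Dil and in RA-Dex against RA was not shown, and for Fkbp5 it was 0.64 ± 0.227 (adjusted p = 0.824). Of the 7309 probe sets, 409 had an unadjusted p under 0.05. The count of 1 was 22 with no filter, 2 without Dil replicate a and 2 without Dex replicate b.

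Several lists shifted in the interaction without any member of them passing. The smooth muscle and myofibroblast markers had a median of 0.45, with 13 of 13 measured genes above 0, and the elastic fibre genes 0.38, with 10 of 12 above 0 (camera adjusted p = 2.7e-05 and 0.000888). Both list calls were lost with an estimated correlation (adjusted p = 0.147 and 0.212), and without RA replicate b the smooth muscle median was 0.277 (0.00254). The contractile genes Myh11 (0.64 ± 0.227) and Acta2 (0.45 ± 0.174) and the elastic fibre gene Ltbp2 (0.84 ± 0.243) had adjusted p of 0.811, 0.858 and 0.763. The heart and skeletal muscle markers had a median of 0.57 in the same contrast (camera adjusted p = 2.7e-05, and 0.147 with an estimated correlation), and the Dil arrays, in which muscle and squamous transcripts stood high, enter it.

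The average effect of retinoic acid, 4 arrays against 4, asks what was left of the day 3 treatment, averaged over the day 4 treatment. Inmt, an enzyme that methylates indoles and is abundant in lung, rose 4.0-fold (log2 fold change 2.0 ± 0.13, adjusted p = 4.7e-05). Igfbp6 rose 1.67-fold (0.74 ± 0.109, adjusted p = 0.0404). The interferon-stimulated gene Isg15 fell to 0.431 (-1.22 ± 0.154, adjusted p = 0.0163), and the protease cathepsin E, Ctse, to 0.531 (-0.91 ± 0.138, adjusted p = 0.0467). Phf7 (-0.84 ± 0.131, with 1 other probe set of opposite sign), Tent5c (-0.81 ± 0.128) and the mitotic cyclin Ccnb2 (-0.61 ± 0.097) each fell with an adjusted p of 0.0498. Also called were a second probe set of Ctse, Erdr1 (a rise), a probe set shared by the Sprr2a genes of squamous epithelium (a fall) and one without a gene symbol (a rise), the last 3 chosen after their values were seen. The Erdr1 call rests mostly on its low Dex arrays, at 260 and 307. The Sprr2a call came from the Dil arrays alone, with signals of 4484 and 1447 there and 77.0 to 117 in the 6 others. For Ctse the value in RA against Dil was -0.31 ± 0.196 (adjusted p = 0.75).

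The cell cycle genes were lower as a list after retinoic acid, by a median of -0.44, with 33 of 34 measured genes below 0 (camera adjusted p = 2.88e-26, and 0.005 with an estimated correlation). Over all genes only Ccnb2 passed, and 22 fell when adjusted over the list alone. The call of Ccnb2 was lost with no filter, with no intensity trend, with the replicate letter as a block, and in every fit without 1 array. Kif20a (-0.73 ± 0.128, adjusted p = 0.0872), Cdk1 (-0.57 ± 0.123, 0.191) and Cdc20 (-0.55 ± 0.119, 0.191), all genes of mitosis, had the next smallest p. The list stayed past the threshold in all 17 settings, with medians of -0.469 to -0.412. The cholesterol synthesis genes (-0.30), the erythroid markers (-0.26), the neutrophil markers (0.47), the immediate early genes (0.23) and the inflammatory genes (0.30) passed camera with adjusted p of 7.02e-05, 0.000102, 4.95e-05, 0.000102 and 0.026. With an estimated correlation these lists had adjusted p = 0.0722, 0.0976, 0.0722, 0.0976 and 0.313, and the inflammatory call was lost without Dil replicate b (0.0852), RA replicate b (0.332) or RA-Dex replicate b (0.239). That call was also lost with the stricter filter (adjusted p = 0.0951) and the mean over all probe sets of a gene (0.0711). Its median was 0.097 with no filter (adjusted p = 0.273), 0.524 without RA-Dex replicate a (0.000491) and 0.118 without RA-Dex replicate b. The erythroid median was -0.159 without Dil replicate a (adjusted p = 0.000165), -0.398 without Dil replicate b (0.00157), -0.393 without Dex replicate a (0.000479) and -0.158 without Dex replicate b (0.000696), and the immediate early median 0.138 without RA replicate a (0.00397). No member of these 5 lists passed over all genes, and adjusted over the list alone 1 cholesterol and 3 erythroid genes fell and 2 neutrophil, 1 immediate early and 1 inflammatory gene rose. The inflammatory values rest on Vcam1, Ccl6, Ccl9 and Icam1, as the probe sets of the other members were below the filter. The 14 measured retinoid-responsive and retinoid-handling genes had a median of 0.15 (camera adjusted p = 0.0791), and 0 passed over all genes or adjusted over the list alone in limma. Probe sets of the members Cyp26a1, Crabp2, Stra6, Rara, Cdx1 and Hoxb4 were below the filter, and Rarb had none. The result does not speak for these genes.

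With retinoic acid, 4 probe sets rose and 7 fell, and 460 had an unadjusted p under 0.05. Inmt kept its call under every alternative, whereas Igfbp6, Isg15, Ctse, Phf7, Tent5c and Ccnb2 all lost theirs without Dex replicate a (adjusted p = 0.0862 to 0.294), RA-Dex replicate a (0.1 to 0.183) or RA-Dex replicate b (0.0985 to 0.313), and each of the other 5 arrays ended the call of at least 1 of them. All 6 also lost theirs with no filter (adjusted p = 0.0656 to 0.211) and with no intensity trend (0.115 to 0.349). Cyclic loess normalization ended the calls of Phf7 and Tent5c (0.0502 and 0.0531). The replicate letter as a block ended all of these calls but that of Isg15 (adjusted p = 0.116 to 0.139). The count of 11 was 23 with no filter, 2 of them shared with the 11, and 2 with no intensity trend; it was 2 without Dil replicate b, Dex replicate a or RA-Dex replicate a, 3 without RA-Dex replicate b, 6 without Dex replicate b or RA replicate a, and 19 without RA replicate b.

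RA against Dil gives the retinoic acid effect without dexamethasone, and Inmt rose 3.76-fold (log2 fold change 1.91 ± 0.184, n = 2 against 2, adjusted p = 0.00484). The cell cycle genes had a median of -0.61, with 31 of 34 below 0 (camera adjusted p = 3.03e-18, and 0.0103 with an estimated correlation; 0 fell over all genes and 15 adjusted over the list alone, and 584 of all probe sets had an unadjusted p under 0.05 in limma). The other called probe set, chosen after its values were seen, is shared by the Sprr2a genes of squamous epithelium. It fell, from signals of 4484 and 1447 in the Dil arrays to 104 and 92.6 in the RA arrays, and the Dex and RA-Dex arrays were at 77.0 to 117. Muscle and squamous transcripts stood high in these Dil arrays. The call of Inmt was lost with no filter (adjusted p = 0.0618) and with no intensity trend (0.0502), and the count of 2 became 11, 0 and, under the stricter filter, 1; it was 5 without either Dil replicate and 16 without RA replicate b.

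In RA against Dil, 10 more lists passed camera while 0 of their genes passed in limma. With an estimated correlation these lists had adjusted p = 0.0921 to 0.361. Below 0 were the erythroid (median -0.52), cholesterol synthesis (-0.40), elastic fibre (-0.31), heart and skeletal muscle (-0.30), smooth muscle (-0.25) and collagen (-0.11) lists, and above 0 the inflammatory (0.66), neutrophil (0.61), immediate early (0.35) and macrophage (0.17) lists. The inflammatory median again rests on Vcam1, Ccl6, Ccl9 and Icam1. Adjusted over the list alone, 3 erythroid and 1 elastic fibre gene fell, and 3 neutrophil, 2 macrophage and 1 immediate early gene rose. Elastic fibre, collagen and inflammatory calls were lost without Dil replicate b (adjusted p = 0.164, 0.0701 and 0.108) or RA replicate b (0.173, 0.0568 and 0.639), and the macrophage call without Dil replicate a (0.142) or RA replicate a (0.0881). With no filter the inflammatory median was 0.03 and its call was lost (adjusted p = 0.492), and the erythroid median was -0.303 (0.0112). With the mean over all probe sets of a gene the elastic fibre median was -0.181 (0.00668) and the inflammatory median 0.388 (0.0772), and the stricter filter ended the macrophage and inflammatory calls (0.074 for each). The macrophage median was 0.108 under that filter, 0.062 without Dil replicate a and 0.279 without Dil replicate b (0.0061). Without Dil replicate a the erythroid median was -0.279 (0.000643), and without Dil replicate b the cholesterol median -0.26 (0.012).

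RA-Dex against Dex, 2 arrays against 2, gives the retinoic acid effect in lungs that also received dexamethasone, and it uses no Dil array. Inmt rose 4.25-fold (log2 fold change 2.09 ± 0.184, adjusted p = 0.00101) and Erdr1 20.0-fold (4.32 ± 0.159, adjusted p = 2.33e-07, with 1 other probe set of opposite sign). The rise of Erdr1 came from the low Dex arrays, at 260 and 307. Its signals were 5591 and 5723 in RA-Dex and 7064 and 8363 in Dil. Ercc1 fell to 0.266 (-1.91 ± 0.252) and Ctse to 0.35 (-1.51 ± 0.196), each with an adjusted p of 0.0154. The fall of Ercc1 came from the same RA-Dex arrays as its fall in RA-Dex against RA, and Ercc1 was not lower in RA than in Dil. The cell cycle genes had a median of -0.38 with all 34 below 0 (camera adjusted p = 1.43e-11, and 0.0253 with an estimated correlation). Kdr had a value of 0.66 ± 0.173 (adjusted p = 0.693). With a probe set of the immunoglobulin kappa genes and one without a gene symbol, both risen and chosen after their values were seen, 4 probe sets rose and 3 fell, and 302 had an unadjusted p under 0.05.

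The retinoid-responsive genes had a median of 0.27 in RA-Dex against Dex, with 12 of 14 above 0 and 0 past the threshold in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.000729, and 0.101 with an estimated correlation). With no filter its median was 0.113 and the call was lost (adjusted p = 0.289). The 14 genes again leave out Cyp26a1, Crabp2 and Rara. Also past camera were the neutrophil (0.23), heart and skeletal muscle (0.23), glucocorticoid-responsive (0.18), smooth muscle (0.15), endothelial (0.15) and elastic fibre (0.14) lists above 0 and the cholesterol synthesis list below (-0.30). With an estimated correlation these had adjusted p = 0.101 to 0.318, and 1 neutrophil gene rose adjusted over the list alone. The elastic fibre call was also lost with quantile (adjusted p = 0.0761) and cyclic loess normalization (0.0755), the stricter filter (0.0799), no intensity trend (0.056) and the mean over all probe sets of a gene (0.0719), and the cholesterol call with the stricter filter (0.0574). The muscle median was 0.15 with no filter (adjusted p = 0.0125) and the glucocorticoid median 0.11 with the mean over all probe sets of a gene (0.00891). Without RA-Dex replicate a the glucocorticoid, smooth muscle, endothelial, elastic fibre and cholesterol calls were lost (adjusted p = 0.102, 0.269, 0.198, 0.417 and 0.102), and without Dex replicate a the last 4 of these (0.251, 0.159, 0.692 and 0.0732). The neutrophil median was 0.422 without Dex replicate a (adjusted p = 0.00307) and 0.449 without RA-Dex replicate a (0.00462). Without RA-Dex replicate a the muscle median was 0.376 (0.00412), the retinoid median 0.164 (0.0389) and the smooth muscle median 0.063. The elastic fibre median was 0.045 without Dex replicate a, 0.291 without Dex replicate b (0.0048), 0.05 without RA-Dex replicate a and 0.294 without RA-Dex replicate b (0.0118). The endothelial median was 0.096 without Dex replicate a and 0.09 without RA-Dex replicate a, and the smooth muscle median 0.231 without RA-Dex replicate b (0.00727). The calls of Ercc1 and Ctse were lost without Dex replicate a (adjusted p = 0.19 for each), Dex replicate b (0.0865 for each), RA-Dex replicate a (0.203 for each) or RA-Dex replicate b (0.141 and 0.0526), with no filter (0.102 and 0.122) and, for Ctse, with no intensity trend (0.0839). The count of 7 was 16 with no filter, 3 with no intensity trend, 4 without Dex replicate a, 2 without RA-Dex replicate a and 3 without RA-Dex replicate b.

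RA-Dex against Dil gives what still differed from the control arm after both treatments. Igfbp3 rose 11.3-fold (log2 fold change 3.5 ± 0.186, n = 2 against 2, adjusted p = 1.13e-05), Zbtb16 11.3-fold (3.49 ± 0.199), Inmt 7.29-fold (2.87 ± 0.184) and Pdk4 6.96-fold (2.80 ± 0.225). Cxcl12 fell to 0.247 (-2.02 ± 0.182), Meox2 to 0.255 (-1.97 ± 0.218) and Adh1 to 0.308 (-1.70 ± 0.177). Kdr had a value of -0.40 ± 0.173 (adjusted p = 0.281). Of 25 glucocorticoid-responsive genes 18 rose and 0 fell (19 and 0 adjusted over the list alone; median 1.44, camera adjusted p = 6.62e-30, and 0.00442 with an estimated correlation). The cell cycle genes had a median of -0.38, with 5 falls among 34 (7 adjusted over the list alone; camera adjusted p = 9.6e-07, and 0.0384 with an estimated correlation), among them Mcm3 (-1.30 ± 0.177). The count of 5 falls was 3 without Dil replicate a, 2 without Dil replicate b, 1 without RA-Dex replicate a or RA-Dex replicate b, and 2 with no filter.

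The type I cell (0.36), cholesterol synthesis (-0.39) and immediate early (0.10) lists passed camera in RA-Dex against Dil with adjusted p of 0.00691, 0.0095 and 0.00691. With an estimated correlation these lists had adjusted p = 0.308, 0.24 and 0.285, and the immediate early median was 0.261 with the stricter filter (adjusted p = 0.000498), 0.154 with quantile and 0.166 with cyclic loess normalization (0.0101 and 0.00908). That median was 0.265 without Dil replicate b (adjusted p = 0.00789), 0.158 without RA-Dex replicate a (0.0206) and 0.154 without RA-Dex replicate b (0.00653). Falls of the muscle gene Myl1 (-2.36 ± 0.344) and the squamous gene Sprr2b (-1.69 ± 0.297) moved with the muscle and squamous transcripts that stood high in the Dil arrays. In all 188 probe sets rose and 105 fell; the count of 293 fell to 147 with no filter, 165 with no intensity trend, 184 without Dil replicate a, 143 without Dil replicate b, 128 without RA-Dex replicate a and 93 without RA-Dex replicate b. The calls of Myl1 and Sprr2b were lost with no filter (adjusted p = 0.107 and 0.173), and that of Sprr2b also without Dil replicate a (adjusted p = 0.0544) and without RA-Dex replicate b (0.119).

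**Figure D3:**
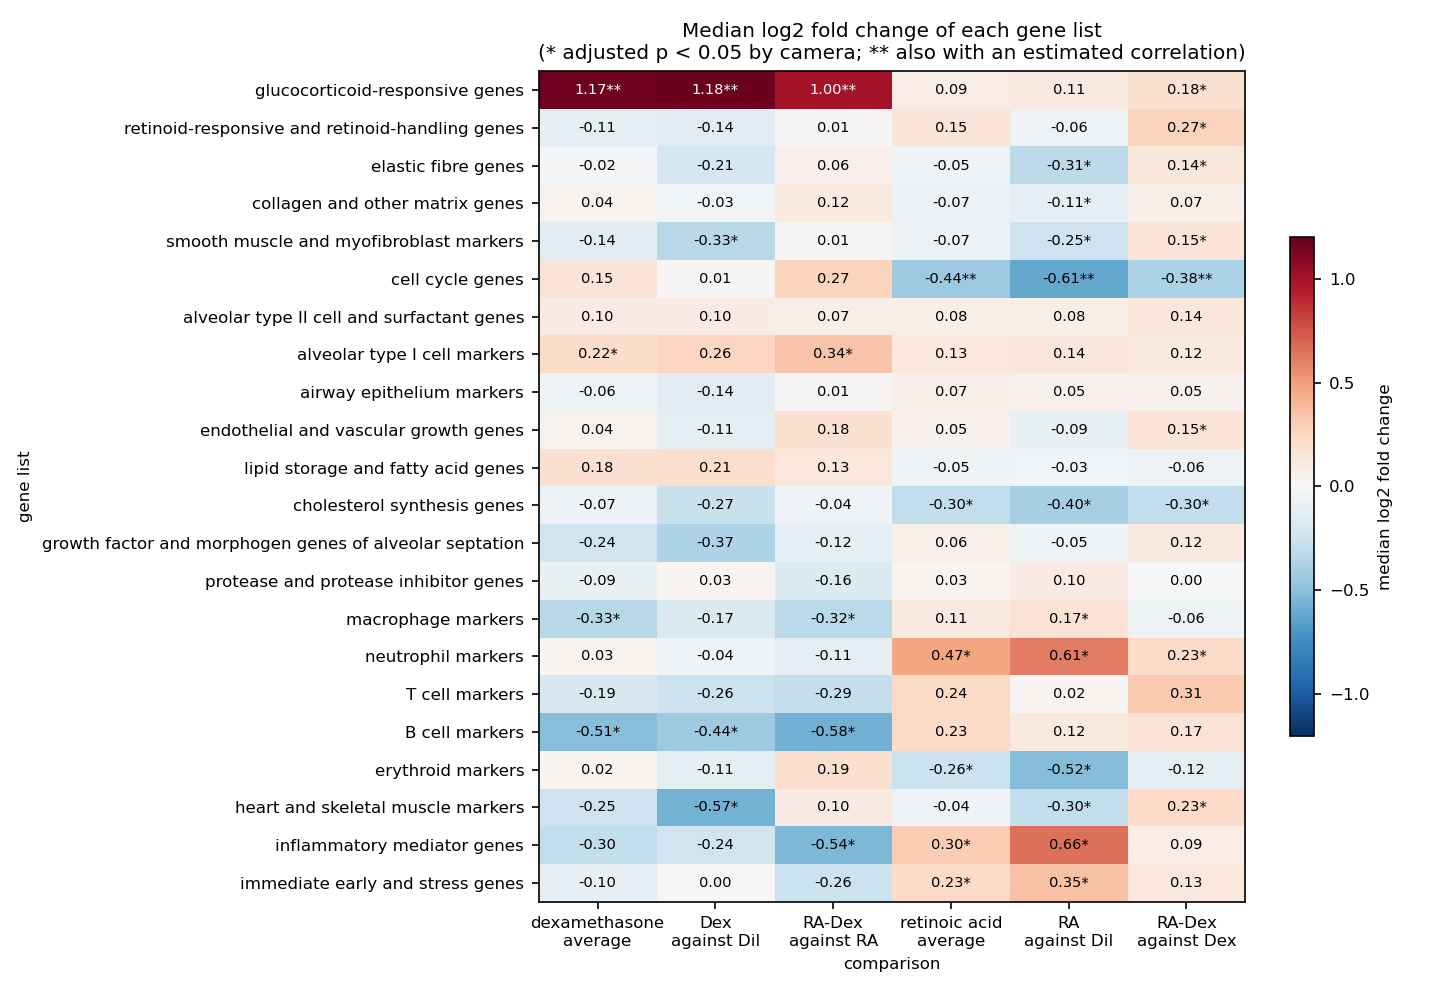
Median log2 fold change of each of the 22 fixed gene lists (listed down the side) in 6 contrasts (along the bottom), on a colour scale in log2 units, with asterisks for camera calls. The glucocorticoid-responsive genes stood at 1.0 to 1.18 in the dexamethasone contrasts, and the cell cycle genes at -0.61 to -0.38 in the retinoic acid contrasts, the only lists called there also with an estimated correlation.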

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

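The tests of another genetic background, of tissue from outside the lung and of a lowering of squamous genes in the lung itself were chosen after the results they measure were seen. The results below met the test of a difference between the dexamethasone effect with and without retinoic acid. With 2 arrays per group, no test for a single array far from its group applied.

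The interaction of Erdr1 was 3.55 (± 0.225 SE, limma adjusted p = 6.8e-05), with 1 other probe set of opposite sign. The retinoid-responsive list had an interaction median of 0.28 (12 of 14 genes above 0, camera adjusted p = 0.0104), the elastic fibre genes 0.38 (10 of 12, 0.000888), the collagen and matrix genes 0.19 (21 of 29, 0.0142) and the smooth muscle markers 0.45 (13 of 13, 2.7e-05). With an estimated correlation these 4 calls were lost (adjusted p = 0.148, 0.212, 0.148 and 0.147). The cell cycle genes had a median of 0.24 (25 of 34 above 0, 0.0102), the endothelial genes 0.26 (17 of 22, 0.00756), the macrophage markers -0.16 (10 of 14 below 0, 0.0283) and the heart and skeletal muscle markers 0.57 (8 of 9 above 0, 2.7e-05). These 4 calls were lost as well (adjusted p = 0.148, 0.212, 0.212 and 0.147 with an estimated correlation). In limma 0 genes of the 8 lists passed, and 2 muscle genes rose adjusted over the list alone. Retinoid, cell cycle, endothelial, collagen and macrophage calls were lost without RA replicate b (adjusted p = 0.0574, 0.0929, 0.0574, 0.0511 and 0.0522) or RA-Dex replicate a (0.07, 0.0539, 0.0539, 0.0539 and 0.102). Without Dil replicate a the cell cycle, endothelial and macrophage calls were lost (0.0549, 0.0549 and 0.127), without Dex replicate a the collagen and macrophage calls (0.0673 and 0.0987), and without RA replicate a the macrophage call (0.104). Without RA replicate b the medians of the smooth muscle, cell cycle, endothelial and macrophage lists were 0.277 (adjusted p = 0.00254), 0.16, 0.158 and -0.241, and the macrophage median was -0.281 without Dil replicate b (0.0155) and -0.302 without RA-Dex replicate b (0.0149). With no filter the retinoid median was 0.092 and its call was lost (adjusted p = 0.362), as was the collagen call (0.0593); both normalizations ended the collagen call (0.0721 and 0.0578) and the stricter filter the macrophage call (0.103).

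Erdr1 and Cad were among 8 probe sets on which both Dex arrays stood apart from all 6 others by over 1 log2 unit. Noise of single arrays gave at most 4 such probe sets over the 24 pairs of arrays that are not an arm, which argues against it as the whole source. Retinoic acid opposing the whole dexamethasone response would move genes back in RA-Dex, but genes picked with 1 Dex array and measured with the other moved by a mean of -0.0745, further rather than back. The risen genes moved by -0.0989 (-0.0467 to 0.0404 simulated with no retinoic acid effect) and the fallen ones by -0.0501 (-0.06 to 0.0527). A simulated reversal by 50% gave 0.442 to 0.551 and 0.311 to 0.433, and 0.396 to 0.485 for the mean. These values argue against a reversal of that size over the whole response. A smaller opposition, or one of fallen genes alone, stays open. The bound set beforehand does not decide for risen genes on the far side, and a simulated range excludes nothing by itself. The simulated noise was independent between probe sets, so the ranges are too narrow where genes vary together on an array. The simulations with no effect also picked more genes, 220 to 255 risen and 192 to 226 fallen, against 200 and 178 observed. Of the genes called in Dex against Dil, fallen ones had a median of 0.196 in RA-Dex against Dex (0.0859 to 0.162 with no effect, 0.429 to 0.499 with the reversal), and risen ones 0.0593, again further (-0.104 to -0.0568 with no effect). Animals of another genetic background in the Dex arm cannot be told apart from the treatment itself, since another arm had up to 4 such probe sets and each arm may differ by litter; Nnt, chosen after its values were seen and known to carry a deletion in some mouse substrains, was the probe set higher in Dex (1334 and 1227).

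Transcripts of squamous epithelium and skeletal muscle were higher in the Dil arrays: Krt4, chosen after its values were seen, was at 4680 and 2550 there against 899 to 1970 elsewhere. Both Dil arrays were above all 6 others for 52.2% of 23 such markers, against 5.3% of all probe sets and 3.57% by chance, but the markers were listed after such transcripts had been seen high there, so this share restates the pattern. Tissue from outside the lung carried into the Dil samples therefore cannot be told apart from a difference between the arms themselves. A lowering of squamous genes by both treatments in the lung itself stays open too, because the share of skeletal muscle markers with that order, 58.3% against 45.5% of the squamous ones, comes from the same markers. Of 4 cartilage markers above the floor, also listed after the data were seen, 1 (25%) had both Dil arrays above all 6 others. Without both Dil arrays, RA-Dex against RA gave 253 called probe sets and RA-Dex against Dex 7. Neither contrast contains a Dil array, so only the pooled variance could change, and these counts decide nothing about the Dil samples.

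Cell cycle genes were lower after retinoic acid. The Dil arrays alone are argued against as the source by RA-Dex against Dex, which leaves them out and gave a median of -0.38, and a change of all genes by scaling by a median of -0.438 at the highest under both normalizations. The splits of the 8 arrays into 4 and 4 numbered 34. For dexamethasone the real grouping gave 576 called probe sets (retinoic acid as a covariate), and another split at most 1. The other splits leave the dexamethasone effect in their residual spread and were bound to call few, so they cannot exclude chance. Nor do the labels say whether a and b are separate animals. For retinoic acid the real grouping gave 3 probe sets (dexamethasone as a covariate) and another split 2. No exclusion of chance is rested on that difference of 1 probe set. What lowered these genes stays open, and a difference in growth or litter between the arms was not tested.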

How the results depend on the processing

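The fits without both Dil or both Dex arrays were chosen after the data were seen. Of 986 results, only those past the threshold in the main fit could be counted as reversed, and 0 of them were. A change of sign in the others was not counted as a reversal. Over all alternatives 14112 values were the same, 698 weaker, 131 stronger and 48 moved. With no filter, which tests more probe sets, the counts of changed probe sets were 349 for the dexamethasone average, 23 for the retinoic acid average, 96 for Dex against Dil, 143 for RA-Dex against RA, 11 for RA against Dil, 16 for RA-Dex against Dex, 147 for RA-Dex against Dil and 22 for the interaction. With no intensity trend they were 2 for the retinoic acid average, 112 for Dex against Dil, 126 for RA-Dex against RA, 0 for RA against Dil (584 at an unadjusted p under 0.05 in limma with the trend), 3 for RA-Dex against Dex and 165 for RA-Dex against Dil. The stricter filter gave 1 for RA against Dil. The labels do not say that the replicate letter pairs the samples, and the deviations of same-lettered arrays from their group means correlated at -0.221 to 0.136 between groups. With the letter as a replicate block, the retinoic acid average had 5 and RA-Dex against Dil 195. The correlation of the dexamethasone effects was 0.375 with no filter and 0.625 with the stricter filter, and the move back of dexamethasone genes was -0.052 under quantile normalization and -0.041 with no filter. Apart from the filters, the cause was not tested.

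Leaving out 1 array gave counts from 309 to 537 for the dexamethasone average, 2 to 19 for the retinoic acid average, 80 to 273 for Dex against Dil, 81 to 250 for RA-Dex against RA, 2 to 16 for RA against Dil, 2 to 7 for RA-Dex against Dex, 93 to 334 for RA-Dex against Dil, and 1 to 2 for the interaction. Signals near the floor of 85.3, which 23.4% to 25.7% of probe sets of an array were at or under, give no fold change, so falls of weakly expressed genes are missed or understated.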

Other observations

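The gene lists in this part, and the tests on them, were chosen after the data were seen, and they were not run under the alternatives. Each list was drawn up around changes already seen, so its tests restate those changes and are not independent evidence of them. Cd52, Irf8, Per1, Per2 and Mmp8 were chosen after their values were seen. Genes expressed across white blood cells were lower after dexamethasone as a list: of 19 measured, 12 fell and 0 rose (16 and 0 adjusted over the list alone), all 19 were below 0, and the median was -0.81 (camera adjusted p = 4.23e-12, and 0.01 with an estimated correlation). Cd52, a surface protein of lymphocytes and monocytes, had a log2 fold change of -1.32 ± 0.137 (n = 4 against 4, limma adjusted p = 0.000172), and Irf8, a transcription factor of monocytes and B cells, -1.08 ± 0.14 (adjusted p = 0.000802). The list was lower both without retinoic acid (median -0.76, adjusted p = 0.0107 with an estimated correlation) and after it (-0.79, 0.019). Of 14 circadian clock genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), among them Per1 (1.67) and Per2 (1.36), with a median of 0.19 (camera adjusted p = 0.000835). This list had adjusted p = 0.0921 with an estimated correlation. Mmp8, the collagenase of neutrophils, was below the filter and not tested, with signals of 44.7 and 49.7 in Dil, 44.1 and 41.9 in RA, 364 and 391 in Dex and 300 and 515 in RA-Dex.

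The DNA replication and mitotic parts of the cell cycle list were separated after the values of its members had been seen, so their camera tests are left out. After dexamethasone, 6 of 15 DNA replication genes fell and 0 rose (7 and 0 adjusted over the list alone; median -0.25), while of 18 mitotic genes 17 were above 0 and 1 rose (1 adjusted over the list alone; median 0.36). After retinoic acid the replication genes had a median of -0.35 (14 of 15 below 0) and the mitotic genes -0.54 (18 of 18 below 0), and 0 and 1 of them fell (1 and 15 adjusted over the list alone). Of 10 interferon-stimulated genes 9 were below 0 after retinoic acid, with a median of -0.37, and 1, Isg15, fell (4 adjusted over the list alone; adjusted p = 0.0133 with an estimated correlation). The call of Isg15 was lost without Dex replicate a (adjusted p = 0.0862), Dil replicate b (0.0599), RA-Dex replicate a (0.1) or RA-Dex replicate b (0.108), with no filter (0.102) and with no intensity trend (0.115). Squamous markers had a median of -0.89 after retinoic acid, and skeletal muscle markers -0.68 after dexamethasone. These had adjusted p = 0.0509 and 0.144 with an estimated correlation. The Dil arrays, in which such transcripts stood high, enter both averages. In contrasts without a Dil array the medians were -0.2 for squamous markers (RA-Dex against Dex) and -0.37 for skeletal muscle markers (RA-Dex against RA).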
